A study of Mus musculus with 11 samples.

How the data were processed

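The deposited matrix held whole-number UMI counts per gene and cell, which the authors made with Cell Ranger 3.0.0 against the mm10 mouse genome, per the submitters' processing notes. Each UMI (unique molecular identifier) stands for 1 captured RNA molecule, and the 3' method counts transcript ends, so exons upstream of the 3' end are not covered. A cell table from the authors gave each cell's library, day, batch, storage, number of pooled mice and cell type. Cells had been filtered by the authors at limits not given in the sources used here, and the lowest UMI count of a cell was 498 to 504 per library.

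The matrix described 14 libraries and 68224 cells. The 11 libraries with a sample here, 55603 cells, were used, and 3 libraries with 12621 cells that matched no sample were left out. By the cell table, those left out include a library of day 0 and another of day 7, both of a batch B. Of 30406 gene rows, 597 that carried a placeholder in place of a gene identity were left out of gene tests (0.517% of counts), which left 29809 genes. The 28 cell types of the authors were joined into 16 classes by their names. No squamous type was among these names, so the planned trends, lists and shares of squamous cells by the authors' names were not run and basal keratin counts were used. The groups were uninjured, 9 DSS days and Il10-/-, with 1 library each. The batch label C covers days 7, 11 and 18 (fresh, 3 mice each by the cell table). The other libraries carry no batch label in the sample records, and the cell table gives them as batch A, frozen, from 8 mice each. They are called the libraries with no batch label here. Gene positions came from the GENCODE vM21 annotation of mm10.

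Day trends were tested on counts summed per library and class over the 9 DSS libraries, in classes with at least 20 cells in at least 7 of them. The model was edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling, filterByExpr) with day, in units of 10 days, and batch label as terms, and genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Adjusted p values of genes are from edgeR unless another tool is named. The classes columnar epithelial, fibroblast, blood endothelial and monocyte or macrophage were fixed before the data were examined, as were 17 lists of cell state genes, 21 lists of cell type markers, the tests, most alternatives and the rule for named genes. The neutrophil class, tests of the batch label within classes and of a slope difference between batch labels, type shares within a class, and thinning of keratin counts were added after the data were seen. Lists with at least 3 tested members were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01 and again with an estimated one. Some lists share members, so their results are not independent in any class. Saa3 is on the antimicrobial, inflammatory fibroblast and inflammatory myeloid lists. The antimicrobial and myeloid lists also share Nos2, S100a8 and S100a9, the fibroblast and myeloid lists Il6 and Ptgs2, and the antimicrobial and fibroblast lists Cxcl5.

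The rule named, per class, the 8 rising and 8 falling genes with the largest slopes among those called whose CPM in the class was at least that of the other cells. For ratios to the uninjured library it named the 8 highest and 8 lowest in columnar cells and the 4 highest and 4 lowest in the other classes, among genes seen in at least 5% of the cells, plus the 2 to 4 members of a discussed list with the largest change. Unnamed predicted genes and mitochondrial genes were counted but not named.

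Shares of cells have exact Clopper-Pearson 95% intervals. Their trends with day used Spearman's rho and Pearson's r with exact two-sided permutation tests over all orders, adjusted over 16 classes. One library against the 9 DSS libraries could not give a two-sided p below 0.2, so shares against the uninjured library were not tested. Ratios to the uninjured library used CPM of the class, genes with at least 20 counts in 1 of the pair, and exact Poisson 95% intervals. A gene with 0 counts was set at 3 counts, which gives an "at least" ratio and not an exact limit, and list medians hold such genes at that bound. Medians were ranked among 10000 random lists matched in 20 expression bins. Genes with at least a 4-fold ratio were counted.

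The steps were tested on simulated data. Of genes with an added slope of 1 log2 unit per 10 days, 48.5% were recovered in columnar cells, 64.0% in fibroblasts, 70.1% in endothelial cells, 67.7% in macrophages and 29.0% in neutrophils. At a slope of 2 the shares were 93.0%, 98.0%, 99.0%, 96.0% and 82.7%. False calls were 4.08%, 4.19% and 4.05% of calls in the first 3 classes, and 8.43% in macrophages and 7.69% in neutrophils, above the 5% aimed at. Ratios were simulated for columnar cells on day 6 alone, from the uninjured profile with Poisson noise and no variation between pools. The changed genes had at least 20 expected counts before the change. Of 8-fold changes, 100% higher and 98% lower were counted, and of 5-fold changes 100% and 94%, with 3 other genes of 8496 counted. These values do not cover differences between animals or the classes with fewer cells.

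Alternatives were DESeq2 1.42.0 (size factors, and its Wald test), no filter on low counts, no batch term, the 6 libraries with no batch label, days 16 to 23 against days 6 to 12, cells with at least 1000 UMIs and under 10% mitochondrial counts, cells without doublets called by Scrublet (scanpy 1.11.5, expected rate 6%), and each DSS library left out in turn. For ratios they were TMM scaling, a count minimum of 50, the stricter cells and thinning to equal totals. Scrublet marked 0% to 1.56% of a library's cells, under 0.5% in most, so it did not work as a filter here, and leaving out the 5% of cells with the highest doublet scores was added, as was leaving out the Car4 epithelial type, whose median mitochondrial share was 50.7%. Other versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.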

Results

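Single-cell 3' RNA sequencing was carried out on the colonic mucosa of mice in 11 groups, with 1 library per group. A control library came from uninjured wild-type mice. Libraries at 9 time points came from wild-type mice given 3% dextran sulfate sodium (DSS), a polysaccharide in the drinking water that injures the colonic epithelium, for 6 days. These mice were sampled on days 6, 7, 9, 11 and 12 and on days 16, 18, 19 and 23 after the first exposure. The last library came from Il10-/- mice, which lack the anti-inflammatory cytokine interleukin 10 and develop colitis without a chemical injury. The Il10-/- mice were about 10 months old and the others about 2 months. Each library was a pool of 3 to 8 mice and stands for its group alone, so no test between a pair of groups was possible. Day trends were tested across the 9 DSS libraries, and intervals for single libraries cover counting error only.

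The 11 libraries held 55603 cells. Total counts were 9028380 in 1820 uninjured cells, 7922350 in 2465 cells on day 6, 17138020 in 4596 cells on day 9 and 13298628 in 4103 cells on day 12. They were 15642825 in 3793 cells on day 16, 16835596 in 4454 cells on day 19, 17056091 in 3285 cells on day 23 and 24785337 in 5831 Il10-/- cells. The libraries of days 7, 11 and 18, labelled batch C and processed fresh, were deeper, with 79011976 counts in 7568 cells, 87012379 in 8953 cells and 80185992 in 8735 cells. Median UMIs per cell were 4579 to 7809.5 in batch C and 2116.5 to 3714 in the other libraries. The median mitochondrial share of a cell was 12.8% in the uninjured library and 3.10% to 9.00% in the DSS libraries. Among columnar epithelial cells it was 34.7% in the uninjured library, 31.6% on day 6, 22.4% on day 23 and 27.9% in the Il10-/- library.

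The first question was which cell classes made up the captured cells of each library during injury, repair and chronic inflammation. Shares are of cells captured and kept by the authors' filter, which may differ from those in the tissue. A larger share of some classes also lowers the share of the others. The uninjured library was mostly fibroblasts, at 42.7% of cells (exact binomial 95% interval 40.4% to 45.0%), and columnar epithelial cells, at 38.9% (36.7% to 41.2%). No neutrophil was among its 1820 cells, which allows a share of up to 0.165% (3 cells of the total). On day 6, neutrophils made up 21.5% of cells (19.9% to 23.2%) and monocytes or macrophages 40.2% (38.3% to 42.2%), against 3.68% (2.86% to 4.65%) in the uninjured library. The highest neutrophil share was 46.8% (45.8% to 47.9%) on day 11, and on day 23 it was 7.43% (6.55% to 8.38%). T cells, dendritic cells and neutrophils lay above the uninjured share in all 9 DSS libraries, and fibroblasts and enteroendocrine cells lay below it in all 9. Columnar cells lay below it in 8 of 9, with 49.9% of cells on day 18 as the exception. Macrophages lay above it in 8 of 9, with 1.92% on day 18 as the exception. The T cell and dendritic cell differences were small in places. The uninjured library held 1 dendritic cell and day 6 held 3, and the lowest T cell share of a DSS library was 2.35%. The Il10-/- library was rich in lymphocytes, with 22.6% T cells (21.5% to 23.7%) and 22.1% B cells (21.1% to 23.2%), against 2.09% and 2.91% in the uninjured library. It held 6.09% neutrophils (5.49% to 6.73%).

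**Figure D1:**
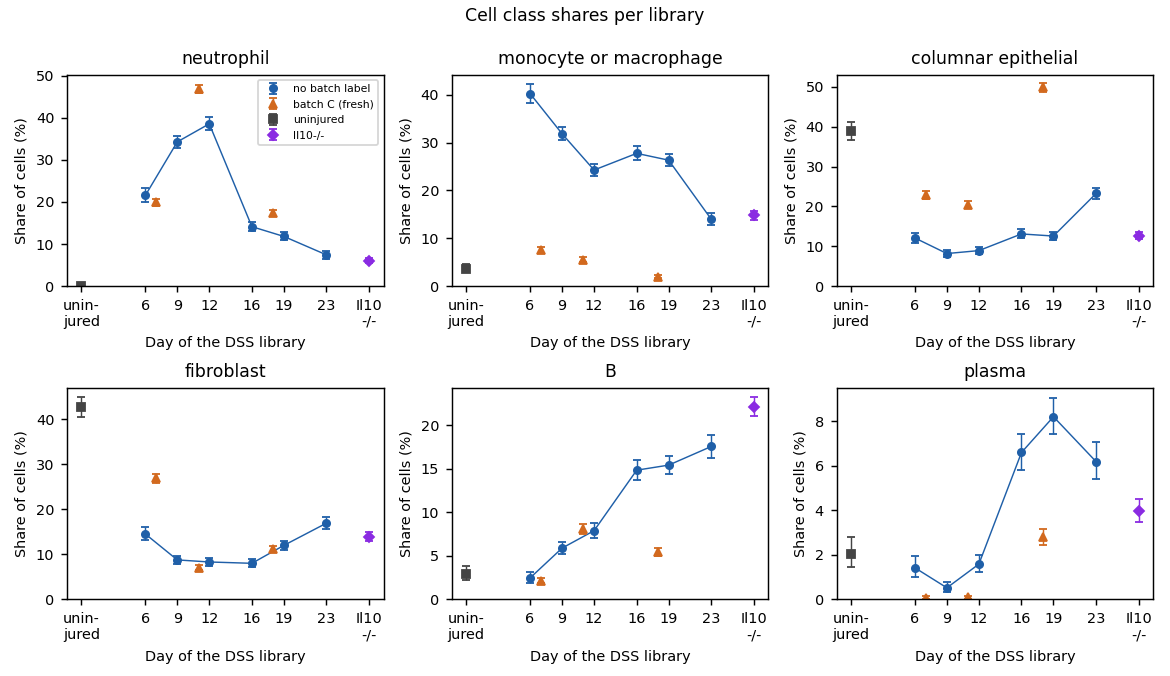
Share of each library's cells (%) in 6 classes against the day of the DSS library, with the uninjured library on the left and the Il10-/- library on the right; bars are exact 95% binomial intervals, and the line joins the 6 DSS libraries with no batch label. The neutrophil share peaked at 46.8% on day 11, and the B cell share among the 6 joined libraries went from 2.47% on day 6 to 17.6% on day 23.

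B cells and antibody-secreting plasma cells had larger shares late in the DSS course. Across the 9 DSS libraries, the B cell share had rho = 0.80 with day (exact permutation p = 0.0138, adjusted over 16 classes 0.111) and r = 0.844 (exact p = 0.00565, adjusted 0.0831). The plasma cell share had rho = 0.80 (exact p = 0.0138, adjusted 0.111) and r = 0.810 (exact p = 0.0104, adjusted 0.0831). Without days 19 and 23, the 2 libraries farthest from the median day, r was 0.644 for B cells (exact permutation p = 0.110) and 0.682 for plasma cells (exact permutation p = 0.0758), so over the 9 libraries neither relation passed without them. Within the 6 DSS libraries with no batch label, the B cell share rose in order of day from 2.47% to 17.6% (rho = 1, r = 0.976, exact p = 0.00278 for both, the smallest that 6 libraries can give, adjusted 0.0444). Without days 6 and 23, r for B cells among the remaining 4 was 0.966. The plasma cell share within these 6 had r = 0.849 (exact p = 0.0556). The neutrophil share had rho = -0.683 (exact p = 0.0503, adjusted 0.201) and r = -0.574 over the 9 libraries, -0.241 without days 19 and 23, and rho = -0.771 and r = -0.715 within the 6. No class passed the threshold over the 9 libraries. Without day 18, the B cell share did (rho = 0.952, r = 0.976, adjusted exact permutation p = 0.0183 and 0.00159). The macrophage share did not overlap between batch C (1.92% to 7.60%) and the other DSS libraries (13.97% to 40.2%). Its relation over the 9 libraries, which entered the adjustment over 16 classes, is therefore not given. Within the 6 it had rho = -0.829 (exact p = 0.0583) and r = -0.884 (exact p = 0.0181, adjusted 0.0963). Blood endothelial cells, whose shares also did not overlap between the batches, had rho = 0.943 within the 6 (exact p = 0.0167, adjusted 0.133).

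The next comparisons asked which genes changed inside each cell class as the mucosa went from acute injury to repair. In columnar epithelial cells, Clu, which encodes clusterin, a secreted chaperone that marks a regenerative epithelial state, rose by 3.05 ± 0.39 log2 units per 10 days (SE, 9 libraries, adjusted p = 0.0197). Its level was 2.04 CPM (counts of the gene scaled by the total count of the class) on day 6 and 106 on day 23, against 3.01 in the uninjured library. Clu lies on chromosome 14 from 65968483 to 65981547 (mm10). Ceacam10, a member of the carcinoembryonic antigen family, rose by 1.69 ± 0.21 (adjusted p = 0.0197), Ramp1, a receptor subunit for the neuropeptide CGRP, by 1.36 ± 0.16 (adjusted p = 0.0197), and Trim46 by 1.05 ± 0.17 (adjusted p = 0.0498). Of the 21 genes that fell, the naming rule took Il5ra, the interleukin 5 receptor subunit that also marks eosinophils (-3.01 ± 0.32), and Eid3 (-1.72 ± 0.27). In all, 4 genes rose and 21 fell of 10914 tested, and 1454 had an unadjusted p under 0.05.

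Transcripts of inflamed stroma and of myeloid cells fell together within columnar cells. The inflammatory fibroblast, myeloid and antimicrobial lists share members, among them Saa3, so their falls are not independent. The inflammatory fibroblast list had 16 tested members, of which 3 fell and none rose over all genes tested, and 13 fell when adjusted over the list alone (median -1.51, adjusted p = 2.76e-23, adjusted p = 0.0376 with an estimated correlation). Its members included Mmp13, a collagenase (-3.62, adjusted p = 0.0226), and Il11, an interleukin 6 family cytokine (-3.17, adjusted p = 0.0197). Sfrp1 (-1.86) and the growth factor gene Nrg1 (-3.06) fell among 5 crypt niche genes (4 adjusted over the list alone, median -1.86, adjusted p = 0.0468 with an estimated correlation). None of 18 inflammatory myeloid genes passed over all genes and 13 fell adjusted over the list alone (median -1.42, adjusted p = 0.0468 with an estimated correlation), with S100a8 at -2.52. None of 14 epithelial antimicrobial genes passed over all genes and 8 fell adjusted over the list alone (median -1.50, adjusted p = 5.02e-13, adjusted p = 0.0468 with an estimated correlation), led by the siderophore-binding gene Lcn2 (-3.34, adjusted p = 0.0751). For 13 fibrillar matrix genes the counts were 0 and 11 (median -1.21, adjusted p = 0.0468 with an estimated correlation). Marker genes of other cell types also moved in this class: fibroblast markers had a median of -1.23 (0 of 8 called), neutrophil markers -2.30 (1 of 7, Mmp9), plasma cell markers 3.15 (0 of 5), and columnar markers themselves -0.01.

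Goblet cell genes rose as a list in columnar cells, with none of 10 passing over all genes and 3 rising adjusted over the list alone (median 0.88, adjusted p = 2.42e-07). That call was lost with an estimated correlation (adjusted p = 0.171). The goblet type was 5.03% of columnar cells on day 6, 2.73% on day 12, 18.5% on day 18 and 10.2% on day 23, with r = 0.495 with day over the 9 libraries (exact permutation p = 0.174) and 0.841 within the 6 with no batch label. The transcription factor gene Atoh1 had a slope of 1.54 (adjusted p = 0.153) and the goblet gene Spink4 0.98 (adjusted p = 0.148). Wnt target and stem cell genes had a median of 0.53 (0 of 10 over all genes or adjusted over the list alone, adjusted p = 0.0398, adjusted p = 0.445 with an estimated correlation). Of 10 fetal-like genes, Clu rose over all genes, and adjusted over the list alone 1 rose and 4 fell, among them the EGF receptor ligand Ereg (-1.88, adjusted p = 0.062). The median of that list was -0.81 (adjusted p = 0.000264, adjusted p = 0.283 with an estimated correlation). Endothelial activation genes had a median of -0.81 (1 of 6 fell, Lrg1, -2.22, adjusted p = 0.0453, and adjusted over the list alone 1 rose and 2 fell), with adjusted p = 0.0462, and adjusted p = 0.322 with an estimated correlation. Surface colonocyte genes (median -0.20), proliferation genes (0.21), interferon genes (median -0.12 and mean -0.00, with the test pointing up), dissociation stress genes (-0.15), resident macrophage genes (0.33), angiogenesis genes (-0.23), squamous basal genes (-0.13) and squamous suprabasal genes (-0.46) did not pass as lists. In the 6 libraries with no batch label, camera with the preset correlation called interferon genes (median 0.45, adjusted p = 0.000422) and resident macrophage genes (0.63, adjusted p = 0.0304) up. The Wnt target and endothelial activation lists did not pass there (adjusted p = 0.452 and 0.721).

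The 25 columnar calls depended on single libraries. Leaving out day 6 gave 52 genes, day 7 gave 179, day 9 gave 16, day 11 gave 112, day 12 gave 4, day 16 gave 4, day 18 gave 1, day 19 gave 14 and day 23 gave 9. All 25 were also called by DESeq2, which called 353, and 14 of them were called in the 6 libraries with no batch label. In stricter cells 2 of the 25 were still called (9 were not tested), and with no batch term 7 were.

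In fibroblasts, genes of the inflammatory fibroblast list fell with day and fibroblast genes such as Pltp and Adamdec1 rose. Csf3, the gene of the neutrophil growth factor G-CSF, fell by 2.83 ± 0.22 log2 units per 10 days (adjusted p = 0.000238), from 134 CPM on day 6 to 8.11 on day 23, with no count in uninjured fibroblasts. The cytokine genes Lif and Il11 fell by 3.04 ± 0.29 (adjusted p = 0.00147) and 3.33 ± 0.46 (adjusted p = 0.0133), the hyaluronan-degrading gene Cemip by 3.67 ± 0.44 (adjusted p = 0.00661) and Mmp13 by 4.16 ± 0.83 (adjusted p = 0.0464). Il1rl1, the interleukin 33 receptor, fell by 2.92 ± 0.53, the acute-phase gene Saa3 by 2.80 ± 0.45 and the natriuretic peptide gene Nppc by 2.67 ± 0.36. Pltp, a phospholipid transfer protein, rose by 1.53 ± 0.16 (adjusted p = 0.000402), from 47.3 CPM on day 6 to 210.4 on day 23, against 181 in uninjured fibroblasts. Adamdec1, a metalloprotease gene that marks fibroblasts of the colonic lamina propria, rose by 1.52 ± 0.31 and the Wnt ligand gene Wnt10b by 1.86 ± 0.41. The types within the class also differed between libraries: the Adamdec1/Bmp4 type was 20.1% of fibroblasts on day 6, 50.7% on day 19 and 32.2% on day 23 (r = 0.547 with day within the 6 libraries with no batch label, exact permutation p = 0.258), and 49.2% to 52.4% in batch C. Stmn4 (2.19 ± 0.51), Efhd1 (1.63 ± 0.33), Wfdc1 (1.45 ± 0.29), Aard (1.37 ± 0.27) and Lgi3 (1.31 ± 0.35) also rose. Csf3 lies on chromosome 11 from 98701263 to 98703629, Il11 on chromosome 7 from 4772373 to 4782859 and Pltp on chromosome 2 from 164839518 to 164857711 (mm10).

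In fibroblasts 205 genes rose and 273 fell of 10290 tested. Of the 19 inflammatory fibroblast genes, 11 fell and none rose over all genes, and 16 fell adjusted over the list alone (median -1.18, adjusted p = 1.01e-32, adjusted p = 0.0128 with an estimated correlation). Inflammatory myeloid genes (4 of 17 fell, 9 adjusted over the list alone, median -1.36, adjusted p = 0.0453 with an estimated correlation) and epithelial antimicrobial genes (4 of 12 fell, 8 adjusted over the list alone, median -1.83, adjusted p = 0.0128 with an estimated correlation) fell as well. Goblet cell genes rose in this class (3 of 8, and 5 adjusted over the list alone, median 1.04, adjusted p = 0.0473 with an estimated correlation), led by the mucus genes Clca1 (2.10), Fcgbp (2.00) and Muc2 (1.52). Markers of columnar cells moved the same way (median 0.77, with Krt18, Cldn7 and Muc2 called of 14), while neutrophil markers had a median of -1.53 and fibroblast markers -0.09. The fibrillar matrix list did not move as a whole over the 9 libraries (median -0.25, adjusted p = 0.514). Within it Postn (0.77) and Fn1 (0.70), which encode periostin and fibronectin, rose, and 2 rose and 2 fell adjusted over the list alone. In the 6 libraries with no batch label the list fell (median -0.37, adjusted p = 0.0012 from camera with the preset correlation). The estimated correlation was not run there. Lox, a collagen crosslinking enzyme gene, had a slope of -0.78 (adjusted p = 0.0543). The crypt niche list did not pass either (median -0.33, adjusted p = 0.528), although Dkk3 rose (0.76, adjusted p = 0.0337), 1 of 2 that did, and 2 rose and 3 fell adjusted over the list alone. Dissociation stress genes had a median of 0.29 (4 of 16 rose and 2 fell, 7 and 2 adjusted over the list alone, adjusted p = 0.00372, adjusted p = 0.386 with an estimated correlation), with Atf3 at 0.91. In the same class, the angiogenesis list had a median of 0.18 with the test pointing down, and the resident macrophage list a median of 0.31 with a mean of -0.06. Neither passed.

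Leaving out day 6 gave 174 fibroblast genes, day 9 gave 250, day 18 gave 167 and day 19 gave 291. DESeq2 called 475 of the 478 genes again, 242 of them were called in the 6 libraries with no batch label and 89 with no batch term.

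**Figure D2:**
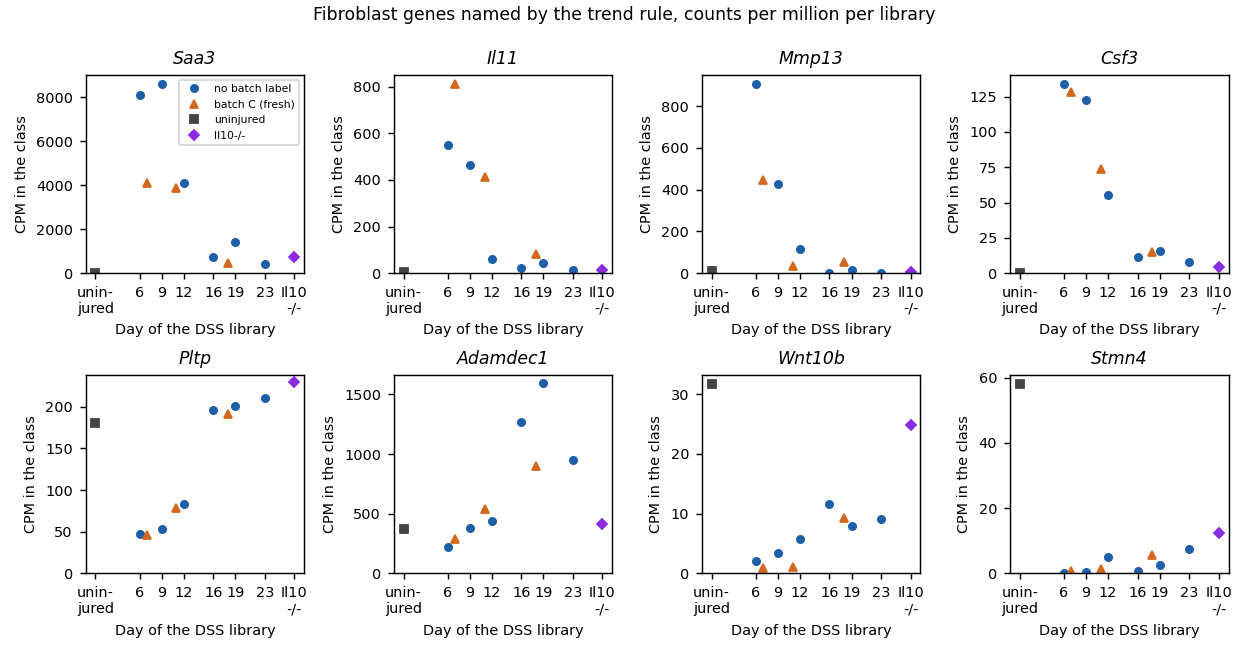
CPM (linear axis) in fibroblasts of each library for 8 genes named by the trend rule, against the day of the DSS library, with the uninjured and Il10-/- libraries at the ends; each point is 1 library. Csf3 went from 134 CPM on day 6 to 8.11 on day 23 and Pltp from 47.3 to 210.4.

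In blood endothelial cells, Tnfaip3 and Tnip1, which encode a feedback inhibitor of NF-kB and its partner, fell by 1.003 ± 0.17 (adjusted p = 0.007) and 1.24 ± 0.22 (adjusted p = 0.00769), and Hif1a, the gene of a hypoxia-responsive transcription factor, fell by 0.80 ± 0.18 (adjusted p = 0.0247). Rnf19b (-1.005) and Mrpl33 (-0.93) also fell. Gas6, a ligand of the TAM receptors that mediate uptake of dying cells, rose by 1.41 ± 0.19 (adjusted p = 0.000699), from 93.4 CPM on day 6 to 345 on day 23, against 319 in the uninjured library. The circadian output gene Dbp (1.55 ± 0.27), Ankrd37 (1.52 ± 0.25), Tppp3 (1.48 ± 0.24), Tcf15 (1.36 ± 0.28), Rgcc (1.26), Ptprr (1.26) and Pltp (1.22 ± 0.22) rose too. Gas6 lies on chromosome 8 from 13465374 to 13494490 (mm10).

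In all, 31 endothelial genes rose and 15 fell of 3537 tested. With DESeq2 52 rose and 62 fell, in stricter cells 35 and 37, and without day 6 35 and 41, so the balance of rising and falling genes is not settled. Genes of endothelial activation, the adhesion molecules and chemokines that recruit leukocytes, fell as a list, with none of 10 passing over all genes and 5 falling adjusted over the list alone (median -0.72, adjusted p = 0.00105, adjusted p = 0.133 with an estimated correlation). P-selectin, Selp, had a slope of -1.57 (adjusted p = 0.0516) and Ackr1, a chemokine-binding receptor of venules, -0.96 (adjusted p = 0.0627). The mix of types in the class moved as well. The authors' Selp/Sele type was 33.3% of blood endothelial cells on day 6 and 13.2% on day 23. Its share had rho = -0.80 with day over the 9 libraries (exact permutation p = 0.0138, adjusted 0.0761). Inflammatory fibroblast genes fell (2 of 6, 5 adjusted over the list alone, median -1.66, adjusted p = 0.0447 with an estimated correlation), among them Saa3 (-2.99). Angiogenesis genes had a median of 0.39 (0 of 10 over all genes, 2 rose adjusted over the list alone, adjusted p = 0.00498, adjusted p = 0.161 with an estimated correlation), with the tip cell gene Esm1 at 1.73 (adjusted p = 0.0875). Interferon genes had a median of 0.31 (0 of 15 over all genes, 1 rose adjusted over the list alone, adjusted p = 0.00491, adjusted p = 0.133 with an estimated correlation), and resident macrophage genes 0.93 (2 of 3, Gas6 and Apoe, also adjusted over the list alone, adjusted p = 0.00145, adjusted p = 0.0944 with an estimated correlation). Dissociation stress genes had a median of 0.50 (3 of 16 rose, 8 adjusted over the list alone, adjusted p = 3.68e-07, adjusted p = 0.133 with an estimated correlation), with Hspb1 at 0.95. The goblet, antimicrobial, myeloid, matrix, proliferation and squamous basal lists also passed with the preset correlation and not with an estimated one (adjusted p = 0.128 to 0.4 with an estimated correlation). The fetal-like list had a median of 0.15 with the test pointing down and did not pass. Columnar markers in this class had a median of 1.17 (0 of 8 called), neutrophil markers -3.17 (0 of 4) and endothelial markers 0.17. Leaving out day 6 gave 76 genes and day 7 gave 78. DESeq2 called 44 of the 46 again, and 15 were called with no batch term.

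More genes were called in monocytes and macrophages than in the other 4 classes. Vcan, the gene of a proteoglycan made by fresh monocytes, fell by 1.65 ± 0.17 (adjusted p = 0.000697), from 277 CPM on day 6 to 39.2 on day 23. Thrombospondin 1, Thbs1, fell by 1.45 ± 0.16 (adjusted p = 0.000677), Chil3, a chitinase-like gene of activated myeloid cells, by 1.83 ± 0.45 (adjusted p = 0.0481), and the protease inhibitor gene Serpinb2 by 1.95 ± 0.32 (adjusted p = 0.00644). Plppr3 (-1.83), Map3k15 (-1.61), Jdp2 (-1.55 ± 0.19) and Apoc1 (-1.45 ± 0.21) fell as well. Hpgds, a prostaglandin D synthase gene, rose by 1.64 ± 0.16 (adjusted p = 0.000243), from 6.69 CPM on day 6 to 47.9 on day 23, against 79.3 in the uninjured library. The receptor gene Gpr34 rose by 2.16 ± 0.28 (adjusted p = 0.000707), H2-M2 by 2.21 ± 0.54, the mitotic kinase gene Bub1 by 1.92 ± 0.55 and the adhesion gene Cadm1 by 1.60 ± 0.27. Gpr162 (1.71), Fam149a (1.65) and Tlr11 (1.60) rose too. Hpgds lies on chromosome 6 from 65117293 to 65144908 and Vcan on chromosome 13 from 89655312 to 89742509 (mm10).

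In this class 531 genes rose and 717 fell of 10058 tested. Of 16 proliferation genes, 12 rose over all genes and 15 adjusted over the list alone (median 1.12, adjusted p = 2.82e-14, adjusted p = 0.139 with an estimated correlation), among them Mcm2 (1.61), Cdk1 (1.43) and Birc5 (1.38). The class joins 2 types of the authors, macrophages (8171 cells over the libraries used) and proliferating macrophages (136 cells). Whether the share of the proliferating type changed with day was not tested. Of 11 resident macrophage genes, 6 rose over all genes and 8 adjusted over the list alone (median 0.97, adjusted p = 1.01e-08, adjusted p = 0.139 with an estimated correlation), among them Cd4 (1.78), Hpgds, Gas6 (1.13) and the complement gene C1qa (1.09). Of 19 interferon and MHC class II genes, 7 rose and 1 fell (8 and 4 adjusted over the list alone). The genes of antigen presentation Cd74 (0.88), H2-Ab1 (0.84) and Ciita (0.83) rose, the interferon-induced gene Ifit1 had a slope of -1.67 (adjusted p = 0.0625), and the list's median was -0.05 with a mean of 0.02 and a test pointing up (adjusted p = 0.0198, adjusted p = 0.424 with an estimated correlation). Inflammatory myeloid genes fell (3 of 19, 5 adjusted over the list alone, median -0.62, adjusted p = 0.00016, adjusted p = 0.351 with an estimated correlation). Matrix genes fell (5 of 11, 7 adjusted over the list alone, median -0.93, adjusted p = 0.139 with an estimated correlation), among them Col3a1 (-1.26) and Sparc (-1.10), as did inflammatory fibroblast genes (5 of 15, 6 adjusted over the list alone, median -1.26, adjusted p = 0.182 with an estimated correlation), among them Mmp3 (-3.03) and Il11 (-3.01). Fibroblast markers fell with them (3 of 8 called, median -0.93), B cell markers rose (3 of 5, median 1.36), plasma cell markers had a median of 2.24, neutrophil markers -1.40 (1 of 7 called, Csf3r) and macrophage markers 0.10. T cell markers had a median of 0.16, and 2 of 5 rose, Cd8a and Cd4, which is also on the resident macrophage list. Whether the rise of Cd4 comes from T cell RNA was not tested. Dissociation stress genes had a median of 0.24 (3 of 16 rose and 1 fell, 5 and 1 adjusted over the list alone, adjusted p = 0.022, adjusted p = 0.424 with an estimated correlation). The goblet, antimicrobial, crypt niche and fetal-like lists passed with the preset correlation alone (adjusted p = 0.139 to 0.182 with an estimated correlation), and no list held with an estimated correlation. Leaving out day 6 gave 815 genes, day 18 gave 760 and day 23 gave 447. DESeq2 called 1051 of the 1248 genes again, 714 were called in the 6 libraries with no batch label and 152 with no batch term.

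**Figure D3:**
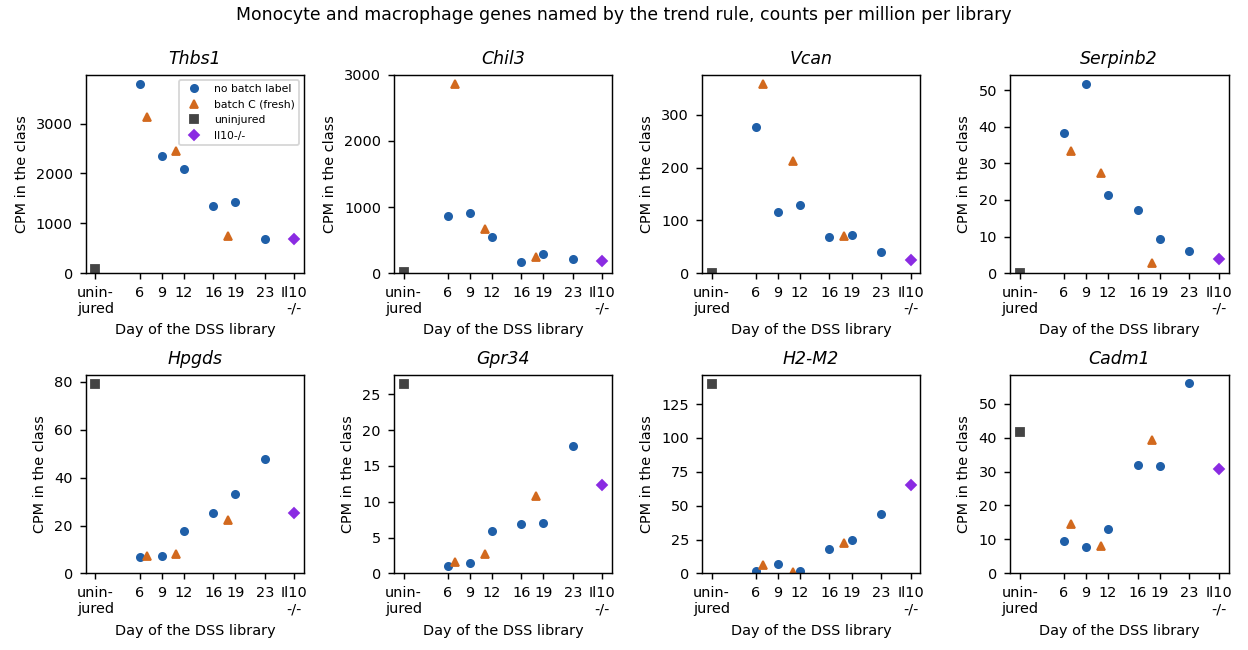
CPM (linear axis) in monocytes and macrophages of each library for 8 genes named by the trend rule, against the day of the DSS library, with the uninjured and Il10-/- libraries at the ends; each point is 1 library. Vcan went from 277 CPM on day 6 to 39.2 on day 23 and Hpgds from 6.69 to 47.9.

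Neutrophils were a class added after the data were seen. Olfm4, the gene of a granule protein found in a subset of neutrophils, fell with day by 2.01 ± 0.23 (adjusted p = 0.0019), from 77.9 CPM on day 6 to 12.9 on day 23, and Lcn2 fell by 1.80 ± 0.27 (adjusted p = 0.0124). Orm1 (-2.96), Ggt1 (-2.84), Csf3 (-2.83), Adpgk (-2.37), the lipase gene Lipg (-1.94 ± 0.30) and Atp13a2 (-1.78) also fell. Meig1 rose by 2.20 ± 0.36 (adjusted p = 0.00798), and AW011738 (1.20), Cd300c2 (0.84), Pttg1 (0.81), Cdc42ep3 (0.76) and Rgs2 (0.72) rose. In all 49 genes rose and 170 fell of 8394 tested, and within the 6 libraries with no batch label 79 rose and 55 fell of 4457, so the balance turned. Epithelial antimicrobial genes (4 of 14 fell, 7 adjusted over the list alone, median -1.05) and inflammatory fibroblast genes (4 of 14, 8 adjusted over the list alone, median -1.49) fell, both with adjusted p = 0.0442 with an estimated correlation. Goblet genes (1 of 9, 7 adjusted over the list alone, median 1.11) and angiogenesis genes (0 of 7, 4 adjusted over the list alone, median 2.10) rose with the preset correlation, each with adjusted p = 0.0673 with an estimated correlation. Neutrophil markers had a median of -0.89 (3 of 7 fell, S100a8, S100a9 and Mmp9), endothelial markers 1.83 (0 of 7 called), fibroblast markers -0.70 (1 of 8, Dcn) and columnar markers 0.57 (2 of 14, Muc2 and Phgr1). Surface colonocyte, Wnt target, proliferation, myeloid and stress lists passed with the preset correlation alone (adjusted p = 0.156 to 0.43 with an estimated correlation). The interferon list (median 0.01, with the test pointing down) and the fetal-like list did not pass. Without day 9 the count was 45, without day 18 it was 35, without day 19 it was 82 and without day 23 it was 49.

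The batch label was tested because the batch C libraries were processed fresh from 3 mice each and the others were frozen from 8 mice each. No day had libraries of both kinds, so the model adjusted for day as a straight line. A course that is not straight could add to the batch term. Over all cells, 2154 genes were higher and 2357 lower in batch C of 14444 tested, and without day 18 the total was 2016. All 11 monocyte or macrophage markers were lower in batch C (median -2.54, range -3.79 to -1.13), as were 6 of 8 dendritic cell markers (median -1.84), 5 of 7 plasma cell markers (-2.68) and 14 of 19 interferon and MHC class II genes (-1.36). Of 10 goblet cell genes, 7 were higher (median 1.54), and 4 of 5 lymphatic endothelial markers were higher (1.25). Fibroblast markers (median 0.01, 0 of 9 called) and neutrophil markers (0.03, 0 of 7) did not differ detectably.

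The state of the mucosa at the end of DSS exposure was compared with the uninjured mucosa within classes. On day 6, columnar cells carried large amounts of antimicrobial and nitric oxide genes. Reg3b and Reg3g, which encode antimicrobial lectins and are close paralogs whose reads may be shared, were 455-fold (95% interval 325 to 657) and 221-fold (146 to 354) higher than in uninjured columnar cells. Nos2, inducible nitric oxide synthase, was 285-fold higher (78.0 to 2363, 2 uninjured counts). The colonocyte gene Clca4b, one of a family of similar genes, was at 824 CPM against 0.694 (3 uninjured counts, ratio interval 406 to 5765). Mptx1, a mucosal pentraxin gene of the colon, was 714-fold lower (279 to 2621), and Reg4, a gene of deep crypt secretory cells, 53.4-fold lower (28.0 to 117). Nos2 lies on chromosome 11 from 78920787 to 78960254 and Mptx1 on chromosome 1 from 174330518 to 174332873 (mm10). Wfdc18 (67.3-fold), the progenitor gene Plet1 (62.3-fold), the interferon-induced gene Ifit2 (185-fold, 32.4 to 7406, 1 uninjured count) and Mfsd2a (60.7-fold, 16.0 to 514, 2 uninjured counts) were also higher. Mettl7a2 (23.6-fold, 4.05 to 949, 1 count on day 6), Cpn1 (16.3-fold), the calcium-binding gene S100g (15.6-fold), Naaladl1 (13.8-fold, 3.67 to 117, 2 counts), Odf3b (10.7-fold, 2.79 to 90.5, 2 counts) and Ttr (9.41-fold) were lower. In cells with at least 1000 UMIs and under 10% mitochondrial counts, the log2 ratio of Cpn1 was 0.02 and that of S100g 0.38, so neither was lower there.

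By list, 11 of 14 measured antimicrobial genes were at least 4-fold higher and none lower in day 6 columnar cells (median log2 ratio 5.63, above all 10000 random lists), as were 12 of 14 interferon genes (2.38). Of 7 fetal-like genes, Ly6c1 (12.98-fold) and Ly6a (6.75-fold), which encode surface proteins induced in regenerating epithelium, were 4-fold higher (list median 1.54). Goblet genes (median -1.12) and surface colonocyte genes (-0.74, with the water channel gene Aqp8 at -1.77) were lower than all random lists. The mix of types differed too. The goblet, Dpep1/Guca2a and Car4/Ly6g types were 8.90%, 12.9% and 19.1% of uninjured columnar cells and 5.03%, 8.05% and 26.2% of day 6 ones. All 14 measured inflammatory myeloid genes and 9 of 12 inflammatory fibroblast genes were also at least 4-fold higher in these columnar cells, with medians of 6.17 and 3.39. Neutrophils were absent from the uninjured library, and on day 6 S100a8 was at 1061.6 CPM in columnar cells and 21804 in the other cells. Proliferation genes had a median of 0.52, Wnt target genes 0.05 and stress genes -0.03. In total 211 genes were at least 4-fold higher and 102 lower of 8663 in columnar cells, and 214 and 57 when thinned to equal totals.

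Day 6 fibroblasts expressed Saa3 at 8118 CPM from 12004 counts, against 1 count in the uninjured library (27163-fold, 4874 to 1072961), with sequence shared in its gene family. The neutrophil chemokine gene Cxcl5 was 1073-fold higher (418 to 3943), Il1rl1 328-fold (127 to 1206) and the stromelysin gene Mmp10 267-fold (140.3 to 586). Stmn4 had no count on day 6 against 194 (at least 28.6-fold lower), and Fam71a (26.96-fold, 4.66 to 1082), Igf2bp3 (26.5-fold, 4.58 to 1065) and Angptl1 (21.2-fold, 5.71 to 178) had 1, 1 and 2 counts. Of the 19 inflammatory fibroblast genes, 15 were at least 4-fold higher (median 4.56), among them Csf3 (at least 149-fold) and Mmp13 (112-fold). Matrix genes had a median of 0.87, with Lox 8.23-fold and the tenascin gene Tnc 7.04-fold higher, and crypt niche genes 0.69, with Nrg1 9.38-fold and the BMP antagonist gene Grem1 8.21-fold higher. In fibroblasts 236 genes were at least 4-fold higher and 159 lower of 9142.

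In day 6 blood endothelial cells, of which there were 27 against 43, the chemokine gene Cxcl1 was 102-fold higher (17.7 to 4070, 1 uninjured count), Csf2rb 29.4-fold (4.76 to 1215, 1 count), Csf3 at least 27.7-fold and Tnfaip3 20.1-fold (5.09 to 173, 2 counts). Of 6 measured activation genes 4 were at least 4-fold higher (median 2.48), among them Lrg1 (11.9-fold) and Selp (11.4-fold), and interferon genes had a median of -1.38. The mix of types differed too: the authors' Selp/Sele type was 33.3% of day 6 endothelial cells (9 of 27) and 9.30% of uninjured ones (4 of 43). Fmo2 and Ptprr (both 12.0-fold, 3.05 to 103), Dbp (10.5-fold, 2.64 to 90.6) and Afdn (8.22-fold, 2.02 to 72.1) were lower, each with 2 counts on day 6. Day 6 macrophages, 992 against 67, were rich in Ifitm1 (568-fold, 102 to 22438), the protease inhibitor gene Slpi (480-fold, 86.1 to 18953), the chemokine gene Cxcl3 (162-fold, 29.1 to 6412) and haptoglobin, Hp (140.2-fold, 25.1 to 5543), each with 1 uninjured count. Ifitm1 belongs to a family of similar genes. Lyz1 (138-fold, a paralog of Lyz2), Fcrls (85.8-fold), Retnla (71.3-fold) and the folate receptor gene Folr2 (at least 71.5-fold) were lower. Of 19 inflammatory myeloid genes 12 were at least 4-fold higher (median 3.44), and of 9 resident macrophage genes 7 were at least 4-fold lower (median -2.77), C1qa by 7.31-fold. Stress genes had a median of -1.17 in macrophages. TMM scaling moved the median of all genes on day 6 by -0.16 in columnar cells and 0.21 in macrophages. The counts at least 4-fold apart were 28 and 25 of 770 in endothelial cells (33 and 14 when thinned to equal totals) and 362 and 118 of 7271 in macrophages (156 and 81 of 2101 when thinned).

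Day 23 was compared in the same way to see how far the mucosa had returned. Columnar cells still differed from uninjured ones, with 299 genes at least 4-fold higher and 60 lower of 9896. Clca4b was 349.8-fold higher (119.5 to 1698, 3 uninjured counts), the goblet cell effector gene Retnlb 107-fold (51.8 to 267), Nos2 86.3-fold (23.7 to 716, 2 uninjured counts) and Reg3b 53.9-fold (38.5 to 77.9). Ifit2 (95.3-fold, 16.9 to 3788, 1 uninjured count), Wfdc18 (70.7-fold), Myl7 (60.6-fold) and Plet1 (52.4-fold) were higher. Reg4 (9.58-fold), Fxyd4 (8.75-fold), Mptx1 (7.67-fold), Mfap3l (5.86-fold), Mettl7a2 (5.25-fold), Slc37a2 (4.67-fold) and Sun2 (4.13-fold) were lower. Antimicrobial genes had a median of 3.76 (10 of 13 at least 4-fold higher), interferon genes 3.08 (16 of 18) and fetal-like genes 0.99 (4 of 9, with Clu 35.2-fold higher). Goblet genes had a median of 0.54 (percentile 88.3 among random lists), with the mucus genes Agr2 5.003-fold and Muc2 4.90-fold higher, and surface colonocyte genes -0.89. Proliferation genes had a median of 0.92, with Cdk1 3.34-fold higher. All 15 measured inflammatory myeloid genes were 4-fold higher (median 4.48) and matrix genes had a median of -1.48 in these columnar cells.

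In day 23 fibroblasts, Saa3 (1448-fold, 259 to 57243, 1 uninjured count), Hp (270.4-fold, 92.0 to 1316, 3 counts), Adamts15 (95.03-fold, 16.4 to 3820, 1 count) and the adhesion gene Chl1 (89.1-fold) were higher. Angptl1 and Engase (both 9.43-fold, Engase with 3 counts on day 23, 3.04 to 47.3), Stmn4 (7.62-fold) and Gap43 (7.02-fold) were lower. Inflammatory fibroblast genes had a median of 1.63 (7 of 16), crypt niche genes 0.93 with Grem1 6.64-fold higher, matrix genes 0.66 with Lox 3.96-fold higher, and interferon genes 1.32 (6 of 16). The counts were 134 and 45 of 9140. In 68 endothelial cells Sox4 (14.4-fold, 2.38 to 586, 1 uninjured count), Cxcl10 (at least 11.2-fold), Esm1 (7.79-fold) and Adgrl2 (6.93-fold, 1.75 to 60.0, 2 counts) were higher. The lymphatic chemokine gene Ccl21a, one of several near-identical copies, had no count against 66 (at least 44.5-fold lower), and Htra1 (7.07-fold), Ptprr (3.59-fold) and Ypel3 (3.45-fold) were lower. Activation genes had a median of 1.72 (3 of 9) and angiogenesis genes 0.88, and the counts were 23 and 4 of 1524. In 459 macrophages Ifitm1 (410.5-fold, 73.6 to 16219, 1 count), Slpi (396-fold, 71.0 to 15638, 1 count), the chemokine gene Ccl5 (185-fold, 51.2 to 1531, 2 counts) and Cxcl3 (123-fold, 22.1 to 4882, 1 count) were higher, and Lyz1 (97.9-fold), Retnla (52.9-fold), Fcrls (23.3-fold) and Cd2 (19.8-fold) lower. Inflammatory myeloid genes had a median of 3.15 (12 of 19) and resident macrophage genes -0.71 (2 of 10 lower). The counts were 227 and 32 of 6508 (84 and 36 of 1959 when thinned to equal totals), and TMM scaling moved the median by -0.19 in columnar cells and 0.16 in macrophages.

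The Il10-/- library addressed chronic colitis without DSS. The Il10 gene, on chromosome 1 from 131019845 to 131024974 (mm10), had 1365 counts in the library labelled Il10-/-, which is 55.1 CPM in 13.03% of cells. The uninjured library had 16 counts (1.77 CPM, 1.01 to 2.88) in 0.330% of cells and the DSS libraries 1.36 CPM on day 18 to 19.96 CPM on day 9. Within the Il10-/- library it was at 302 CPM in lymphatic endothelial cells, 217 in neutrophils, 159 in blood endothelial cells, 108 in T cells, 71.5 in fibroblasts, 50.5 in macrophages and 8.98 in columnar cells, and 18.2% of Il10-/- fibroblasts (median 5152 UMIs) had an Il10 UMI against 6.22% of columnar cells (5213.5 UMIs). A disrupted gene can still be transcribed, and 3' counts outside the disrupted part check nothing. Xist, the transcript that silences an X chromosome in female cells, had 4173 counts in the Il10-/- library and 0 to 8 in the others, while the Y-linked gene Ddx3y was found in every library (74.4 CPM in the Il10-/- library, 58.2 to 110 in the others). Only in the Il10-/- library were both above 8 counts. Other Y-linked genes were not lower there than in all others, with Uty at 13.3 CPM (11.4 to 19.0 in the others), Kdm5d at 8.31 (7.47 to 13.7) and Eif2s3y at 47.3 (43.4 to 57.5). Xist points to female cells in that pool, but their share is not known and the Y-linked genes leave the source of Xist open. Age, and possibly sex, differ along with genotype in every ratio of the Il10-/- library to the uninjured one.

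Columnar cells of the Il10-/- library carried antigen presentation and interferon genes. Cd74, the invariant chain of MHC class II, was 88.6-fold higher than in uninjured columnar cells, H2-Aa 72.2-fold and H2-Ab1 69.3-fold, and 16 of 18 interferon and MHC class II genes were at least 4-fold higher (median 4.58). Ubd, a ubiquitin-like gene induced by interferon and TNF, was 187-fold higher (118 to 316), on chromosome 17 from 37193892 to 37196095 (mm10). Reg3g (498-fold, 329 to 794) and Reg3b (423-fold, 303 to 611), which may share reads, Nos2 (275-fold, 76.0 to 2279, 2 uninjured counts), Lrg1 (227-fold, 77.3 to 1101, 3 counts), Plet1 (188-fold) and Clca4b (1660.2-fold, 568 to 8052, 3 counts) were higher, and Xist, which may reflect sex, was at least 318-fold higher. Mfap3l (11.1-fold), Slc35e3 (6.49-fold), the goblet gene Clca1 (6.04-fold), Naaladl1 (5.45-fold), Odf3b (4.84-fold), Bmp3 (4.84-fold), Clec2e (4.80-fold) and Sgk1 (4.61-fold) were lower. Antimicrobial genes had a median of 5.30 (11 of 14), fetal-like genes 1.02 (3 of 8, with Ly6c1 22.7-fold higher), proliferation genes 0.71, goblet genes -0.65 and surface colonocyte genes -0.78. All 15 measured inflammatory myeloid genes were 4-fold higher here (median 4.20). The counts were 410 and 51 of 9464.

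In Il10-/- fibroblasts, 15 of 18 interferon genes were at least 4-fold higher (median 2.66), led by the T cell chemokine gene Cxcl9 (110.0-fold, 30.2 to 912, 2 uninjured counts), and 4 of 18 inflammatory fibroblast genes were (median 0.89). Saa3 (2425-fold, 435 to 95812, 1 uninjured count), H2-Q6 (452-fold, 80.8 to 17874, 1 count, an MHC gene with close paralogs), Xist (at least 324-fold, which may reflect sex) and Hp (300.4-fold, 103 to 1459, 3 counts) were the highest ratios. Mcm6 (6.68-fold), Angptl7 (5.44-fold), Ramp1 (4.82-fold) and Stmn4 (4.63-fold) were lower. Matrix genes (median 0.03) and crypt niche genes (0.13) were near the uninjured level, and the counts were 291 and 25 of 9887. In 54 endothelial cells the neutrophil calprotectin genes S100a8 and S100a9 were at least 390.4-fold and at least 272-fold higher (S100a8 at 11673.9 CPM, against 9260.92 in all other cells of that library, which held neutrophils where the uninjured one had none), Ubd at least 70.9-fold and Cxcl1 51.3-fold (8.98 to 2047, 1 count). Cytl1 (7.98-fold), the arterial gene Sox17 (4.03-fold), Afdn (3.99-fold) and Htra1 (3.81-fold) were lower. Interferon genes (7 of 16, median 1.85) and activation genes (4 of 8, median 1.91) were higher, and the counts were 60 and 5 of 1326. In 865 macrophages Ifitm1 (321-fold, 57.6 to 12689, 1 count), Ccl5 (62.4-fold, 17.2 to 515, 2 counts), Hp (52.2-fold, 9.34 to 2064, 1 count) and the transglutaminase gene Tgm2 (32.6-fold, 9.00 to 269.5, 2 counts) were higher. Fcrls (20.01-fold), the histone gene Hist1h2ap (11.7-fold, one of many similar copies), Yae1d1 (10.4-fold) and Clec4b1 (10.0-fold) were lower. Inflammatory myeloid genes had a median of 1.92 (9 of 19) and resident macrophage genes -1.69 (6 of 14 lower). In macrophages 182 genes were higher and 103 lower of 8428, and with TMM scaling, which moved the median by 0.26 there and by 0.18 in endothelial cells, 280 were higher and 53 lower. Thinned to equal totals, 78 were higher and 44 lower of 1902.

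**Figure D4:**
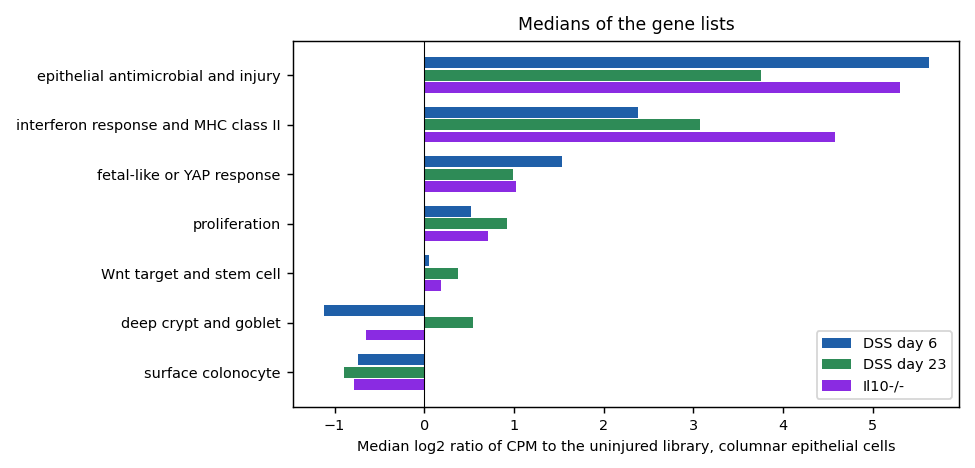
Median log2 ratio of CPM to the uninjured library over the measured members of 7 gene lists in columnar epithelial cells, for day 6, day 23 and the Il10-/- library, 1 library each. Antimicrobial medians were 5.63, 3.76 and 5.30, and the goblet list alone had medians on both sides of 0, at -1.12, 0.54 and -0.65.

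Squamous epithelium was looked for because cells like those of the anal transition zone can enter the injured colon. Cells with at least 2 UMIs over the basal keratin genes Krt5 and Krt14 and the transcription factor gene Trp63 made up 2.02% of epithelial candidates on day 11 (116 of 5730, 1.68% to 2.42%) and 1.97% on day 18 (1.64% to 2.34%, 6342 candidates). In the uninjured library the share was 0.467% (0.127% to 1.19%), on day 7 it was 0.564%, in the other DSS libraries 0% to 0.696%, and in the Il10-/- library 0.394%. In stricter cells the shares were 2.09% on day 11 (1.67% to 2.59%) and 2.67% on day 18, against 1.81% on day 12 (0.591% to 4.18%), 1.11% on day 19 (0.303% to 2.81%), 1.08% on day 9 (0.295% to 2.74%), 1.01% on day 7 (0.552% to 1.68%) and 0.595% in the uninjured library (0.0151% to 3.27%). Day 16 (0.279%, 0.00707% to 1.55%) was the one library whose interval did not overlap that of day 11 there, so day 11 does not stand apart from the uninjured library in stricter cells. Most of these cells were columnar by the authors' types, 102 on day 11 and 113 on day 18. Columnar cells were 1827 of the 5730 candidates on day 11 but 708 of 856 in the uninjured library, so the share of columnar cells is also given. It was 5.58% on day 11, 2.59% on day 18, 0.565% in the uninjured library and 0% to 1.37% in the others. In stricter columnar cells it was 11.6% on day 11, 8.77% on day 12, 7.05% on day 18 and 5.88% on day 19. There it was 1.92% in the uninjured library (1 of 52 cells) and 0% to 4.82% in the others, so day 11 stood less apart. Over all deposited cells, the share among fibroblasts, which should lack these genes, was 0.475% on day 11 and 0.306% on day 18. Their median depths were 13716 and 8938.5 UMIs, against 10235 and 5296.5 in columnar cells. With each cell thinned to 2000 UMIs, the shares were 0.640% on day 11 and 0.622% on day 18, against 0% to 0.230% in the other libraries. Krt14 had 1944 and 1360 counts in those libraries, and Trp63 at most 3 counts in any library. Days 11 and 18 both belong to batch C, as does day 7, where the share was 0.564%. Krt5 had 88, 80 and 108 counts on days 7, 11 and 18, in deeper libraries, and 0 to 5 in the others. Of 9 squamous basal genes, 4 were higher and none lower in batch C over all cells (median 0.63). The batch label alone would also raise day 7, but its interval over all deposited cells (0.323% to 0.914%) lay below those of days 11 and 18. In stricter cells it overlapped that of day 11. No library without the batch label reached such a share over all deposited cells. With 1 library per day, a link to days 11 and 18 therefore cannot be told apart from one to batch C in those libraries.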

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

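The tests of slope differences, and the test of the UMI minimum, were chosen after the results they address had been seen. The test of the UMI minimum replaced an earlier one on median UMIs, whose result had been seen and which the greater depth of batch C made uninformative.

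A test of whether day slopes differ between the batch labels singled out 2 genes in monocytes and macrophages. These were Cyp2c55, a colonocyte gene (slope difference 6.06, batch C minus the others, adjusted p = 7.04e-05), and the matrix gene Ecm1 (-1.997, adjusted p = 0.0186). In neutrophils 42 genes differed, 41 of them with a lower slope in batch C. Those with the lowest p were Col4a2 (-5.37) and Esam (-6.58), and Cyp2c55 was the one gene with a higher slope (4.81). Among the 41 were the blood endothelial markers Pecam1 (-2.93), Cdh5 (-6.14) and Esam, and the smooth muscle or pericyte marker Kcnj8 (-6.82). Whether RNA of those cells in the droplets of neutrophils makes up this difference was not tested. The same edgeR test called 0 genes in columnar cells, fibroblasts and blood endothelial cells, where 591, 630 and 210 had an unadjusted p under 0.05, and DESeq2 was not run for it.

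The first pattern weighed was the low macrophage share of batch C, 1.92% to 7.60% against 13.97% to 40.2%. If the same cells carried other type names, macrophage markers summed over all cells would be level between the batches, but their median was -2.543, with 11 of 11 lower. If macrophages had been lost at the UMI minimum, those left in batch C would crowd near it, but 2.99% of them had under 980 UMIs (2 times the lowest count of any cell over the genes used), against 15.2% to 18.9% in the other DSS libraries. Their median depths were 9562.5 to 11138 UMIs in batch C and 2623.5 to 3589 in the others. The greater depth of batch C, known before this test, made a low value likely, so the test is weak. The split of the libraries by batch label called 4511 genes over all cells. Of the 84 splits into 3 and 6 libraries, 1, the real one, called as many (highest other 3), so chance is an unlikely source of these calls. The splits were not run on the macrophage share. Fresh or frozen cells, the number of mice pooled and any difference between the animals cannot be told apart, since all follow the batch label.

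The second pattern was the near absence of the Dpep1/Guca2a epithelial type from batch C, which held 1 of its 591 cells. The 50 genes that mark these cells were picked in the DSS libraries with no batch label, which by itself favours lower values in batch C. If the cells were present under another type name with these genes unchanged, the genes would have stayed level in batch C columnar cells. Their median was -1.888, with 50 of 50 lower and 33 called. Removing the type alone would give -0.63, so the marking genes were lower than that loss needs and other columnar cells may have carried less of them too. Cells that carried less of these genes could also have been given another type name, which this test cannot tell from missing cells. Fresh or frozen handling and differences between the animals stay open.

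The third pattern was the fall of inflammatory fibroblast transcripts within columnar cells. RNA of fibroblasts in the droplets of columnar cells would keep these genes at the same ratio to fibroblasts as fibroblast markers, but the list's median lay within the range of the 9 markers in 1 of 9 DSS libraries, above it in 7 and below it in 1. The list stood at 0.900% of its fibroblast level on day 6, below the markers (0.973% to 1.98%), within their range on day 9, at 2.10% on day 11 (markers 0.528% to 0.657%) and at 0.572% on day 23 (0.216% to 0.378%). This argues against fibroblast RNA as the only source in 7 libraries but not on days 6 and 9. The median level of the markers themselves went from 1.19% on day 6 to 0.300% on day 23, so a part of fibroblast RNA in the fall stays open. Doublets would lose the slope without the 5% highest doublet scores, but 119.8% of it was left, in a test limited by how poorly the scores worked. RNA from myeloid cells, which share some of these genes, was not tested.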

How the results depend on the processing

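The alternatives without the highest doublet scores and without the Car4 type, and those of the neutrophil class, were chosen after the data were seen. For trend genes called in columnar cells (25), no filter on low counts gave 120, DESeq2 353, no batch term 8, the 6 libraries with no batch label 109, days 16 to 23 against days 6 to 12 gave 74, stricter cells 6, leaving out the highest doublet scores 15 and leaving out the Car4 type 14. Leaving out 1 library gave 1 to 179. For fibroblasts (478), DESeq2 gave 762, no batch term 89, the later against the earlier days 274, and leaving out 1 library 167 to 636. For blood endothelial cells (46), no filter gave 411, DESeq2 114, no batch term 17, the 6 libraries 86, stricter cells 72, and leaving out 1 library 39 to 78. For macrophages (1248), no batch term gave 152, the later against the earlier days 623, and leaving out 1 library 447 to 1368. For neutrophils (219), no filter gave 770, DESeq2 460, no batch term 21, the 6 libraries 134, and leaving out 1 library 35 to 286. The balance of rising and falling genes turned in blood endothelial cells (31 and 15) with no filter (193 and 218), DESeq2 (52 and 62), the later against the earlier days (15 and 21), stricter cells (35 and 37), without day 6 (35 and 41) and without day 9 (27 and 32). It turned in neutrophils (49 and 170) in the 6 libraries (79 and 55), in columnar cells (4 and 21) without day 23 (5 and 4) and without day 18 (1 and 0), and for the batch label (2154 and 2357) with no filter (2376 and 1990) and without day 7 (2595 and 2495). The batch label count (4511) ranged from 2016 to 5090. The causes were not tested.

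With an estimated correlation, 5 lists passed in columnar cells, 1 in blood endothelial cells, 0 in macrophages and 2 in neutrophils. Share trends passing went from 0 to 1 (B cells) in stricter cells and in the 6 libraries, and from 0 to 1 when 1 library was left out. Raising the count minimum to 50, which leaves fewer genes, gave 783, 464 and 673 genes at least 4-fold apart on day 6, on day 23 and in the Il10-/- library, against 1241, 824 and 1127. The other alternatives for these totals stayed within 1.5 times, but counts of single classes moved by more. On day 6, thinning to equal totals gave 156 macrophage genes higher (362), 14 endothelial genes lower (25) and 57 columnar genes lower (102), and stricter cells gave 62 columnar genes lower. On day 23, thinning gave 84 macrophage genes higher (227), 25 fibroblast genes lower (45) and 10 endothelial genes higher and 8 lower (23 and 4). Stricter cells gave 27 columnar genes lower (60) and 2 endothelial genes lower, and TMM scaling 21 macrophage genes lower (32). In the Il10-/- library thinning gave 78 macrophage genes higher and 44 lower (182 and 103), and TMM scaling 280 and 53, with 2 endothelial genes lower (5). With the count minimum of 50, columnar cells had 121 higher and 38 lower on day 6, 179 and 26 on day 23 and 255 and 18 in the Il10-/- library. Fibroblasts had 143 and 88, 66 and 17, and 134 and 15. Endothelial cells had 11 and 5, 6 and 1, and 34 and 3. Macrophages had 328 and 49, 154 and 15, and 182 and 32. In stricter cells the log2 ratio of Cpn1, columnar epithelial, DSS day 6 over uninjured, reversed to 0.0168, and that of S100g, columnar epithelial, DSS day 6 over uninjured, to 0.3793 (22 cells against 52, the cause was not tested). No called gene had a slope of the opposite sign under another setting except 1 gene in stricter neutrophils. Named slopes kept their direction under every alternative run, and Csf3 and Pltp in fibroblasts, Gas6 in blood endothelial cells, and Gpr34, Hpgds, Jdp2, Serpinb2, Thbs1 and Vcan in macrophages kept their call in all of them. Trim46 lost its call in 13 alternatives, Mmp13 in fibroblasts and Chil3 in 12 each, and Eid3 and Lgi3 in 11 each. Of all values of named slopes, 468 kept their call and 112 lost it, and with 1 library left out 404 kept it and 178 lost it. Of the list results under alternatives, 106 stayed as they were, 41 lost their call, 3 gained one and 7 moved otherwise. Of the named ratios, 307 stayed, 51 moved and 2 reversed. The keratin shares were higher in stricter cells in 10 of 11 libraries, and on days 7, 12, 18 and 19 and in the Il10-/- library they lay above the 95% interval of the main share. No paired analysis was possible because each group has 1 library. Trends of a squamous class were not run, as no such type exists among the authors' names. Endothelial ratios rest on 27 to 68 cells per library.

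The real order of the days was set among 100 orders, the others drawn at random within the batch labels. As many genes as in the real order were called in 1 of 100 for columnar cells (highest other 7) and 1 for fibroblasts (177). The number was 2 for blood endothelial cells (46 real, highest other 47), 1 for macrophages (912) and 1 for neutrophils (213). These numbers include the real order, so 1 of 100 is the smallest possible. Chance is made unlikely at that level but is not excluded. In the last 4 classes the highest other order differs from the real one in days 9 and 12 alone.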

Other observations

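The trends of type shares within a class were computed after the data were seen. Endothelial cells of the Selp/Sele type, which carry the selectins that slow rolling leukocytes, had a share of the blood endothelium with rho = -0.80 (exact permutation p = 0.0138, adjusted 0.0761) and r = -0.781 (exact p = 0.0115, adjusted 0.0634) over the 9 DSS libraries, and rho = -0.829 (exact p = 0.0583) within the 6 with no batch label. Goblet cells as a share of columnar cells had r = 0.841 within these 6 (exact permutation p = 0.0417, adjusted 0.168) and r = 0.495 over all 9. No type passed the threshold.

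Within the DSS course Il10 had no count in 58 T cells on day 6, which allows up to 34.97 CPM at 3 counts, and in T cells was at 12.6 CPM on day 7, 62.1 on day 9, 149.99 on day 11, 101 on day 12, 203 on day 16, 26.98 on day 18, 34.6 on day 19 and 114 on day 23. Macrophages had 16.9, 46.2, 29.7, 2.90, 20.7, 11.6, 2.28, 9.41 and 20.4 CPM from day 6 to day 23 in the same order, with no steady course. Columnar cells, which serve as background, had 0.0790 to 1.93 CPM in the DSS libraries. In the Il10-/- library 15.7% of T cells and 15.7% of macrophages had an Il10 UMI, against 30.0% of lymphatic endothelial cells, 29.9% of neutrophils, 24.1% of blood endothelial cells, 18.2% of fibroblasts and 6.22% of columnar cells, at unlike depths (median 1700.5 UMIs in T cells and 5152 in fibroblasts).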
